A study of Homo sapiens with 37 samples.

How the data were processed

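Human RMG-1 cells carrying an inducible hairpin against ARID1A were profiled by several assays, and 4 of the 37 samples had processed files: 1 control and 1 knockdown GRO-seq library (both replicate 2) and 2 ribodepleted total RNA-seq libraries of the knockdown at day 7. The other 33 samples, which cover ChIP-seq, ATAC-seq, chromatin RNA-seq, other RNA-seq and the remaining GRO-seq libraries, were not analysed here. Groups were taken from the sample titles, and 2 ATAC-seq samples whose title and source name disagree were put in no group. Per the labels' protocols, the knockdown was induced with doxycycline for 72 hours, and the day 7 labels give 7 days. The labels do not say whether replicates came from separate cultures.

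The GRO-seq tables deposited by the authors hold raw counts per gene, whole numbers whose totals differ between libraries, for 60308 versioned Ensembl gene IDs of all biotypes. The day 7 tables deposited by the authors hold, per the file headers, transcript length, effective length, expected counts, TPM and FPKM per gene, with the column layout of an RSEM gene table. FPKM values as deposited were used as day 7 levels, expected counts gave the reads behind them, and the deposited TPM values were read only to check that each library had the same sum. FastQC, Trim Galore, BWA, STAR and deepTools are listed in the submitters' processing notes without roles or versions. The genome build, the annotation release, the counting tool and the treatment of multimapping reads are not given in the sources used here, so no coordinates are printed. Whether GRO-seq counting used strand is not given in the sources used here either, so reads of overlapping and antisense genes cannot be told apart. Gene symbols came from a reference table of gene IDs, which matched 55277 of 60308 IDs, and from synonyms in the RefSeq annotation of GRCh38.p14, used for names only. Of the genes on the lists, 5 histones and SOD2, CD24, BOP1 and PECAM1 found no unique match.

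Depth was 2178046 and 2676272 counts in the GRO-seq control and knockdown libraries, with 30705 and 24161 genes above 0. A floor of 3 counts corresponds to 1.38 and 1.12 CPM. GRO-seq counts were scaled by TMM factors (edgeR 4.0.16 in R 4.3.3) computed over genes with a summed count of at least 50. The log2 ratio of knockdown over control used a prior count of 0.5 scaled to library size, and its 95% interval was the exact Clopper-Pearson interval of the share of reads in the knockdown library. A gene counted as higher or lower where the ratio was at least 2-fold and the interval's near bound was beyond 1.5-fold. No quasi-likelihood test was run, because each condition had 1 library. Where a library had 0 counts, the fold is a bound against 3 counts in that library. This bound lies at a larger fold than the near bound of the 95% interval. Reads carried no molecular identifiers, so intervals and bounds cover counting error only. The set of genes behind the TMM factors was not fixed before the data were examined. It was chosen after both candidate values had been seen, a log2 ratio of effective library sizes of 0.20 for the filtered genes and -0.38 for all genes in the tables, and results under the latter are given beside the main ones.

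The calculation was tested on simulated counts with counting noise only, drawn from the GRO-seq library means. It called 97% of 100 genes changed 4-fold, 35% of 100 changed 2-fold and 0 of 8145 unchanged genes, and 96.0% of intervals held the true ratio. The simulation has no variation between libraries beyond counting.

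Gene lists (28) were written from textbook knowledge before the data were examined, including markers of immune, fibroblast, endothelial and neuronal cells, and the p53 and oestrogen receptor lists were included because of the study's subject. Each list's median log2 ratio was placed among 10000 random lists of the same size matched in 20 bins of mean count, as a description of these libraries. Matching also on day 7 RNA level (10 count bins and 4 day 7 classes) was added after the data were examined. Day 7 levels came from knockdown libraries only, so this matching could also remove an effect of the knockdown and is no stricter check. Named genes followed a rule fixed beforehand: ARID1A and ARID1B, the 12 largest ratios in each direction among genes past the 2-fold rule with at least 100 counts, up to 4 members per list by size of the log2 ratio, and at day 7 the 10 highest genes, up to 6 SWI/SNF subunits and 3 members per list by FPKM, and the 6 largest replicate differences at a mean of at least 5 FPKM. LINC00486, MALAT1 and the housekeeping genes, and the subunits SMARCB1 and SMARCA2, were named outside this rule after their values were seen. Each list is illustrated with some of the members the rule allows. Some genes the rule names are not reported here.

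For day 7 RNA, genes with a mean of at least 1 FPKM were counted, and replicates were compared on log2(FPKM + 0.1). Replicate noise was checked by a chi-square of expected counts, rounded to whole numbers, within classes of reads. The ratio of ARID1B to ARID1A was planned as a mean over libraries, but ARID1A had 0 reads in replicate 1, so the ratio of summed reads per effective length is given with its Clopper-Pearson interval. Nascent counts per kb used the transcript length in the day 7 tables. Intervals of correlations and of differences between groups of genes came from 1000 bootstrap draws over genes, except 300 for the background test and its repeat. Alternatives were other scalings (DESeq2 1.42.0 size factors, upper quartile, total count), count minimums of 20, 200 and none, a prior count of 5, other fold rules, FPKM minimums of 0.5 and 5, a pseudocount of 1 and leaving out each day 7 replicate. The planned count minimums also recomputed the scaling factors over the genes that entered. Count minimums of 20, 200 and none with the scaling kept, list medians relative to all genes at minimums of 20 and 200, and relations over genes at 1 FPKM or more with and without a count minimum were added after the data were examined. Calculations other than scaling used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.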

Results

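The series examined how depletion of ARID1A affects transcription in RMG-1, an established cell line of ovarian clear cell carcinoma. ARID1A is a DNA-binding subunit of the canonical BAF form of the SWI/SNF chromatin remodelling complex. It was depleted with a short hairpin RNA induced by doxycycline at 2 µg/ml. The labels list doxycycline for the knockdown samples only. Effects of the drug itself therefore cannot be told apart from those of ARID1A depletion. Of 37 samples, 4 had processed values and 33 were not analysed here. Nascent transcription was measured by GRO-seq, in which nuclei extend engaged RNA polymerases with labelled nucleotides, in 1 control library and 1 knockdown library after 72 hours of doxycycline (replicate 2 of each). Ribodepleted total RNA was measured in 2 knockdown libraries after 7 days of doxycycline, and no control library of that assay was analysed here. The GRO-seq libraries held 2178046 counts (control) and 2676272 counts (knockdown) over 60308 annotated genes. The day 7 libraries held 1328578 and 1879977 estimated reads. With 1 GRO-seq library per condition, differences in nascent RNA have no replicate check, no p-value was computed, and all intervals and bounds cover counting error only.

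The targeted gene, ARID1A (ENSG00000117713), had 332 nascent counts in the control library and 199 in the knockdown library. Its scaled log2 ratio of knockdown over control was -0.94, a ratio of 0.521 with a 95% counting interval of 0.435 to 0.623, which missed the 2-fold rule. ARID1B (ENSG00000049618), its mutually exclusive paralog in the complex, had 141 and 200 counts and a log2 ratio of 0.30 (ratio interval 0.988 to 1.54). Among the 2672 genes with 200 to 1000 summed counts, the ratio of ARID1A lay at percentile 32.9 and that of ARID1B at percentile 60.03. A hairpin acts on mature RNA, so nascent reads over ARID1A do not check the knockdown. The call for ARID1A depended on the scaling: with total counts its ratio was 0.489 (0.407 to 0.583), which passed the 2-fold rule, while its log2 ratio was -0.999 with DESeq2 factors, -0.78 with upper-quartile scaling and -0.36 with factors taken over all genes in the tables, none of which passed. The log2 ratio of ARID1B was 0.21 to 0.88 across these scalings and passed the rule under none of them.

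GRO-seq counts differed widely between the libraries, in both directions. Over genes with a summed count of at least 50, control and knockdown counts correlated at a Spearman rho of only 0.287. On log2 counts the Pearson r was 0.335. Of 8345 genes with a summed count of at least 50, 2375 were at least 2-fold higher and 2322 at least 2-fold lower in the knockdown library, with a counting bound beyond 1.5-fold. The largest ratios towards the knockdown library belonged mostly to pseudogenes, small RNA genes and genes without a symbol. The ubiquitin-ribosomal fusion pseudogene RPS27AP8 had 0 control and 6613 knockdown counts (at least 1915-fold higher), and ENSG00000261120 had 0 and 6947 (at least 2012-fold higher). The small nucleolar RNA gene SNORD13 had 0 and 308 counts (at least 89.2-fold higher). The ribosomal pseudogene RPS20P14 had 5 and 5382 counts, a ratio of 856 (400.5 to 2881), and the U2 small nuclear RNA pseudogene RNU2-36P had 7 and 2100, a ratio of 244 (126 to 649). HMGB3P5 had 2 and 1160 counts, a ratio of 409 (139 to 4166).

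Several protein-coding genes were at or near 0 in the knockdown library. The orphan receptor gene GPR82 had 1296 control and 0 knockdown counts (at least 497-fold lower). CD302 (262 to 0 counts, at least 101-fold lower), CADM4, a cell adhesion gene (250 to 0, at least 95.9-fold), MUTYH, a base excision repair glycosylase gene (248 to 0, at least 95.1-fold), DTYMK, a thymidylate kinase gene (232 to 0, at least 89.0-fold), showed the same form, as did EIF5A2 with 245 and 0 counts. IL7, which encodes a lymphocyte growth factor, had 3842 and 8 counts and was 518-fold lower. The non-coding gene LINC01499 had 5885 and 7 counts and was 899-fold lower. CRHBP had 942 control counts and 1 knockdown count, a ratio of 0.00142 (2.33e-05 to 0.00515), and the pseudogene SUMO2P18 had 1835 and 1, a ratio of 0.000727 (1.20e-05 to 0.00264). Among the 8345 genes with a summed count of at least 50, 23 had 0 counts in the knockdown library and 11 had 0 in the control library. At day 7, measured in knockdown cells only, GPR82, CD302, DTYMK, IL7, LINC01499, CRHBP and SUMO2P18 had 0 reads. CADM4 had 1 read in replicate 1, MUTYH 3 in replicate 2 and EIF5A2 4 in each. RPS27AP8, SNORD13, RNU2-36P and HMGB3P5, higher in the knockdown library, had 0 reads at day 7 as well. Among genes at 0 FPKM at day 7, 1207 were lower and 411 higher, with the cause undecided. These counts alone therefore do not show loss of transcription on knockdown.

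**Figure D1:**
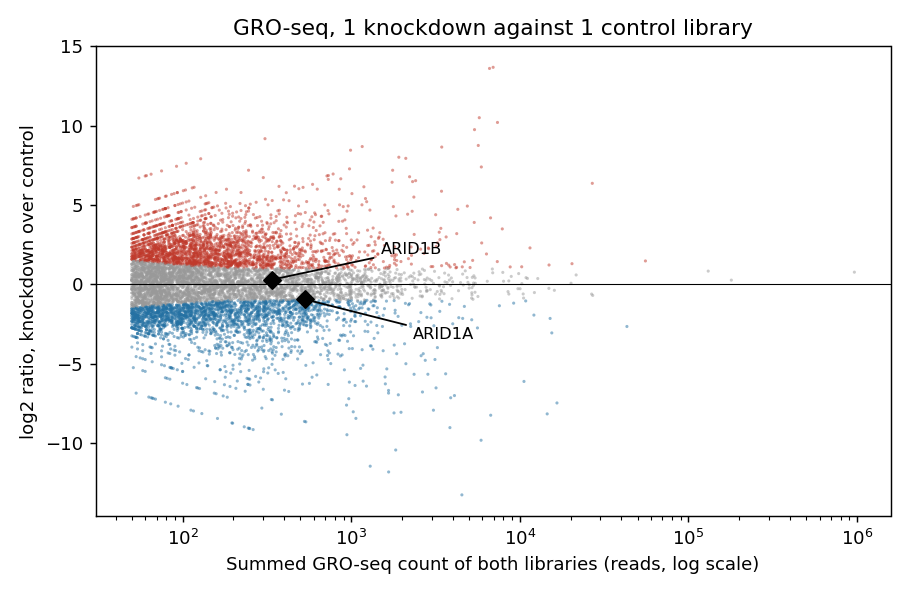
Log2 ratio of nascent RNA (knockdown over control library, vertical axis) against the summed GRO-seq count in reads (horizontal log axis) for 8345 genes, each a point, with 1 library per condition. Red points are the 2375 genes at least 2-fold higher and blue points the 2322 at least 2-fold lower in the knockdown library, ARID1A and ARID1B are black diamonds, and genes at 0 in a library are drawn with a prior count of 0.5, so their height is no measured fold.

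This spread exceeded counting error at every depth. The interquartile range of the log2 ratio was 2.67, against 0.282 when the same counts were redrawn with counting noise alone, and 61.5% of genes were at least 2-fold apart. Among the 220 genes with 2000 or more summed counts, 50.5% were at least 2-fold apart. LINC00486 alone took 14.96% of control and 23.88% of knockdown counts, and MALAT1 took 3.46% and 3.90%. The split between higher and lower genes depended on the scaling and the filter: 50.6% of the genes past the rule were higher in the knockdown library, against 68.6% with scaling factors over all genes in the tables, which put the median log2 ratio at 0.63 in place of 0.05. Without a count filter the share was 64.5% with the factors recomputed over the genes that entered and 40.2% with the factors kept. Gene group medians are therefore given relative to the median of all genes.

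Ribosomal protein genes were higher in the knockdown library as a group. Of 43 measured, 25 were at least 2-fold higher and 2 at least 2-fold lower, and their median lay 1.17 above that of all genes on the log2 scale, at percentile 100 of 10000 random lists matched on count. Across the scalings tried, 23 to 29 were higher and 0 to 3 lower. RPS13 had 12 and 265 counts (18.5-fold higher), RPL28 15 and 279 (15.7-fold), and RPS15 4 and 87 (17.0-fold). Genes of the mitochondrial genome were also higher, 6 of 13 by at least 2-fold and 0 lower, with a median 0.91 above all genes (percentile 99.4). The random lists drew genes singly, so this percentile takes no account of members that vary together. These 13 share the mitochondrial genome and may not be independent. Among these respiratory chain genes MT-ND4L was 19.6-fold, MT-ND6 5.46-fold and MT-CYB 5.15-fold higher. These 13 genes took 0.404% of control and 0.702% of knockdown counts. All mitochondrial genes took 3.03% and 5.65%, of which ribosomal RNA made up 2.58% and 4.88% of all counts. The share of mitochondrial ribosomal RNA was thus higher as well, so the difference was not particular to these 13 genes. Whether mitochondrial transcription or the amount of mitochondrial RNA in the nuclei differed was not tested. Reads of ribosomal protein genes can be shared with their many processed pseudogenes, and how the counting treated such reads is not given in the sources used here.

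Replication-dependent histone genes and genes of the ATF4 and unfolded protein response pathways were the other groups beyond percentile 97.5. Of only 6 measured histone genes, 4 were higher and 1 lower, with a median 3.31 above all genes (percentile 98.9), or 3.11 with H2AC8 set at its bound. H2AC8 had 0 and 61 counts (at least 17.7-fold higher) and H2AC20 had 1 and 79, a ratio of 47.2 (11.97 to 2745), whereas H3C10 had 116 and 16 counts and was 8.11-fold lower. Of 25 measured ATF4 and unfolded protein response genes, 12 were higher and 4 lower, with a median 0.80 above all genes (percentile 98.5). ATF4, the transcription factor of the integrated stress response, had 3 and 219 counts, a ratio of 55.0 (21.4 to 310), and the stress-induced gene NUPR1 had 2 and 135, a ratio of 47.8 (15.9 to 489). Under every scaling tried the medians of these lists were above 0, with 11 to 14 genes of the ATF4 list higher and 1 to 4 lower. HERPUD1 was 6.56-fold higher, and SHMT2, a serine metabolism enzyme gene, was 7.40-fold lower. When random lists were also matched on day 7 RNA level, the percentiles were 100 for ribosomal protein genes, 98.3 for the mitochondrial genome, 96.0 for histones and 82.6 for the ATF4 list. Since day 7 RNA was measured in knockdown cells only, this matching could also remove an effect of the knockdown. The ATF4 list's median relative to all genes was 1.54 at a summed count of at least 20 (28 genes) and -0.057 at one of at least 200 (16 genes). Histone gene copies are near-identical, so their counts are uncertain.

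Further metabolic, stress and lineage groups had positive medians within the range of random lists. Hypoxia and glycolysis genes had a median 1.06 above all genes (percentile 97.05), with 9 of 18 higher and 3 lower. NDRG1 was 11.1-fold and the aldolase gene ALDOA 7.30-fold higher, while ANKRD37 was 8.54-fold lower. Heat shock genes had a median 1.45 above (percentile 96.3), with 5 of 9 higher and 1 lower, and 0.11 above at a summed count of at least 200 (4 genes). The chaperone gene HSPA8 had 2 and 77 counts, a ratio of 27.3 (8.95 to 281), and HSPH1 was 5.35-fold lower. Epithelial genes had a median 0.96 above (percentile 96.2), with 8 of 16 higher and 1 lower. The keratin gene KRT7 was 18.2-fold higher with 9 and 198 counts, and KRT19 was 8.31-fold lower with 13598 and 1882. Mitochondrial ribosome genes (9 of 13 higher, 2 lower; percentile 94.1), ribosome biogenesis genes (3 of 17 higher, 1 lower; percentile 94.01) and oxidative phosphorylation genes (9 of 21 higher, 5 lower; percentile 90.7) lay 1.46, 0.73 and 0.91 above all genes. Counts of members past the 2-fold rule depended on the scaling: across the scalings tried, 3 to 9 ribosome biogenesis genes, 8 to 13 hypoxia genes, 8 to 12 epithelial genes and 9 to 13 oxidative phosphorylation genes were higher, and 2 to 5 of the latter were lower. When random lists were also matched on day 7 RNA level, the percentiles were 78.7 for hypoxia, 83.3 for heat shock, 91.0 for epithelial, 73.3 for mitochondrial ribosome, 85.2 for ribosome biogenesis and 56.6 for oxidative phosphorylation genes. Ribosome biogenesis genes lay 0.18 above all genes at a summed count of at least 200 (7 genes).

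**Figure D2:**
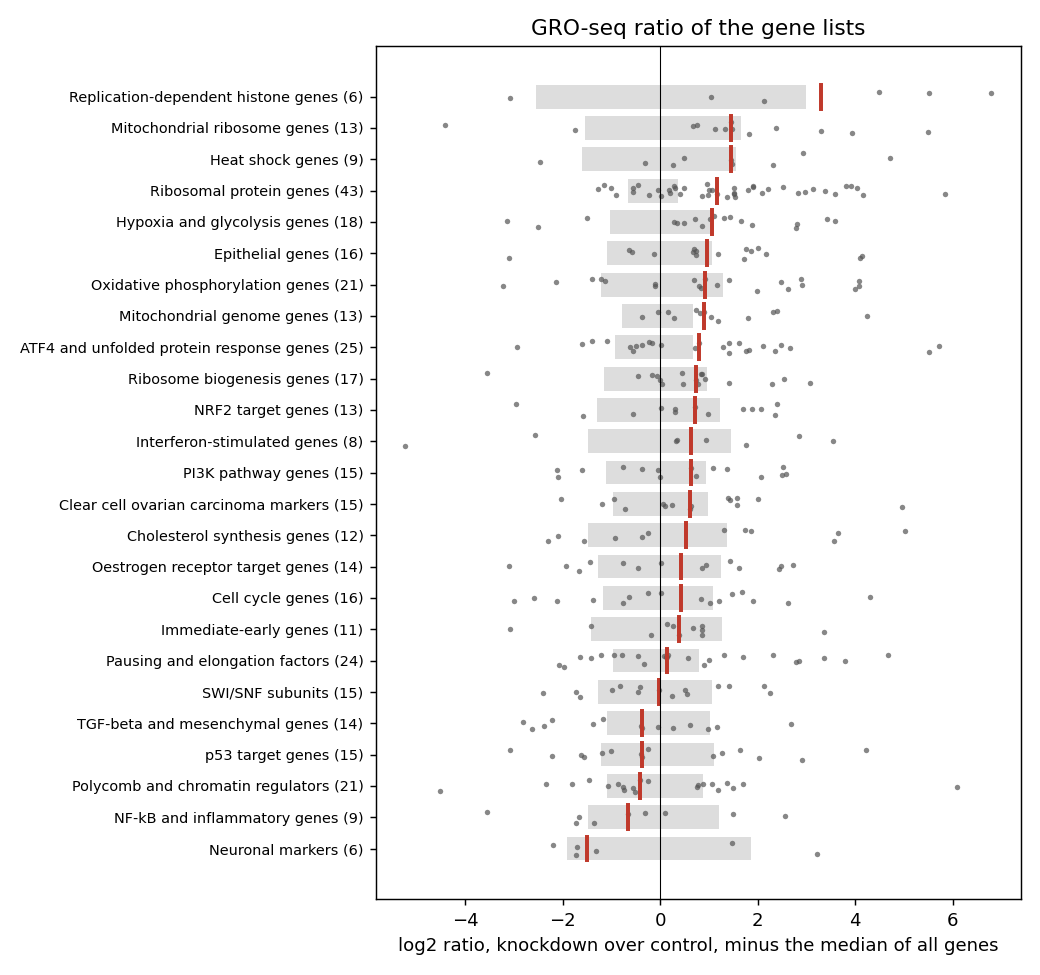
Log2 ratio of nascent RNA (knockdown over control, minus the median of all genes, horizontal axis) for the gene lists with at least 6 measured members, whose number is in parentheses. Points are single genes, the red bar is the list median and the grey band holds the central 95% of medians of 10000 random lists matched on count. The medians of ribosomal protein, mitochondrial genome, histone and ATF4 genes lie to the right of their bands.

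Genes encoding the machinery of polymerase pausing and elongation went both ways, as did genes at large (2375 higher and 2322 lower of 8345). Of 24 measured, 8 were higher and 5 lower in the knockdown library, and their median lay 0.15 above all genes (percentile 70.0, or 14.6 when random lists were also matched on day 7 RNA level). CDK12, a kinase of the polymerase tail, had 136 and 4152 counts and was 26.4-fold higher, the elongation factor gene TCEA1 was 14.3-fold higher, and CCNT2, a cyclin of P-TEFb, was 10.7-fold higher. SWI/SNF subunit genes had a median of -0.027 relative to all genes (percentile 53.9), with 4 of 15 higher and 3 lower, or 4 to 5 and 2 to 4 across the scalings tried. SMARCE1 was 4.92-fold and BRD7 4.51-fold higher, whereas PHF10 was 3.18-fold and DPF3 5.08-fold lower. Polycomb and other chromatin regulator genes had a median of -0.42 relative to all genes (percentile 25.1, or 3.12 when also matched on day 7 level), with 5 of 21 higher and 4 lower. Across the scalings tried, 8 to 11 pausing and elongation genes were higher and 2 to 5 lower, against 5 to 9 and 2 to 5 Polycomb and chromatin regulator genes. The histone methyltransferase gene KMT2D had 14 and 1175 counts and was 70.6-fold higher, and the Polycomb gene BMI1 had 86 and 4 counts and was 21.9-fold lower. The tables give 1 value per gene, so no pausing index could be computed.

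Target genes of p53 and of the oestrogen receptor, themes listed because of the study's subject, also went both ways, as did genes at large. Of 15 measured p53 targets, 4 were higher and 4 lower, with a median of -0.38 relative to all genes (percentile 27.4, or 6.69 when also matched on day 7 level). MDM2, the ubiquitin ligase of p53, was 19.4-fold higher with 15 and 344 counts, and the DNA polymerase gene POLH was 8.20-fold lower with 217 and 30. Of 14 oestrogen receptor targets, 5 were higher and 4 lower (median 0.43 above; percentile 74.5). NRIP1 was 6.84-fold and CCND1, the cyclin D1 gene, 5.65-fold higher, while KRT19 was 8.31-fold lower. Immediate-early genes had 1 of 11 higher and 2 lower (median 0.38 above; percentile 73.7), with EGR1 10.7-fold higher and IER2 8.15-fold lower. Cell cycle genes had 5 of 16 higher and 4 lower (median 0.42 above; percentile 79.2). RRM1, a ribonucleotide reductase gene, was 6.38-fold higher, while the proliferation marker MKI67 had 1047 and 207 counts and was 5.81-fold lower, and PCNA was 7.70-fold lower. Across the scalings tried, 1 to 6 immediate-early genes were higher and 1 to 2 lower, 5 to 8 cell cycle genes were higher and 3 to 4 lower, 4 to 6 p53 targets were higher and 2 to 4 lower, and 4 to 7 oestrogen receptor targets were higher and 1 to 4 lower.

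The signalling and lipid groups showed no common direction beyond random lists. Interferon-stimulated genes had 3 of 8 higher and 2 lower (median 0.64 above all genes; percentile 81.6), with OAS2 7.46-fold higher and PARP9 36.1-fold lower. NF-kB and inflammatory genes had 2 of 9 higher and 4 lower (-0.65 relative to all genes; percentile 19.1), and the chemokine gene CXCL3 was 11.4-fold lower. Cholesterol synthesis genes had 6 of 12 higher and 3 lower (0.53 above; percentile 77.0, or 20.7 when also matched on day 7 level), with SQLE, a squalene epoxidase gene, 4.76-fold lower. NRF2 targets had 6 of 13 higher and 2 lower (0.72 above; percentile 88.1). TGF-beta and mesenchymal genes had 2 of 14 higher and 5 lower (-0.38 relative to all genes; percentile 23.1), with the collagen gene COL5A1 6.77-fold lower. Clear cell carcinoma markers had 6 of 15 higher and 1 lower (0.62 above; percentile 91.2), and PI3K pathway genes had 6 of 15 higher and 3 lower (0.63 above; percentile 92.7), with MTOR 5.96-fold and PIK3CA 5.83-fold higher. At a summed count of at least 200 the median relative to all genes was 1.90 for interferon-stimulated genes (3 genes), -1.23 for NF-kB genes (5 genes), -0.23 for TGF-beta and mesenchymal genes (5 genes) and 0.13 for PI3K pathway genes (9 genes). Across the scalings tried, 2 NF-kB genes were higher and 2 to 4 lower, 2 to 3 TGF-beta and mesenchymal genes were higher and 4 to 5 lower, and 5 to 6 cholesterol synthesis genes were higher and 2 to 3 lower. The higher members numbered 3 to 4 for interferon-stimulated genes, 5 to 7 for NRF2 targets, 6 to 8 for clear cell markers and 6 to 7 for PI3K pathway genes.

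Markers of other cell types were mostly too low to measure. Only 1 of 18 immune markers (CD79A, 5.59-fold lower), 1 of 12 fibroblast markers (PDGFRB, 2.69-fold lower) and 2 endothelial markers reached 50 counts, of which VWF was 2.66-fold lower and FLT1, at a ratio of 1.59 (1.201 to 2.13), missed the rule. The list percentiles were 7.48, 23.3 and 39.7. Of 6 measured neuronal markers, 2 were higher and 4 lower (median -1.51 relative to all genes; percentile 6.91), with SNAP25 9.63-fold higher and ELAVL4 4.44-fold lower. With scaling factors over all genes in the tables, FLT1 had a log2 ratio of 1.25, VWF -0.84 and PDGFRB -0.85. Across all 28 lists, 4 lay at or above percentile 97.5 and 0 at or below 2.5, and 2 and 0 when random lists were also matched on day 7 RNA level. At a summed count of at least 200, where fewer members entered, the median relative to all genes turned negative for oxidative phosphorylation (-1.16), cholesterol synthesis (-0.78), cell cycle (-1.23) and pausing and elongation genes (-0.48) in addition to the ATF4 list, and positive for Polycomb (0.90), p53 target (0.17), endothelial (0.75, 1 gene) and neuronal genes (3.35, 1 gene). It kept its direction but differed by over 1.5 times for SWI/SNF (-0.48) and oestrogen receptor target genes (0.23), besides the heat shock, ribosome biogenesis, interferon, NF-kB, TGF-beta and PI3K lists already given. At a summed count of at least 20 it turned for oestrogen receptor targets (-0.023) and NF-kB genes (0.074). There it differed by over 1.5 times, in the same direction, for pausing and elongation (0.50), cell cycle (0.97), oxidative phosphorylation (1.48), PI3K (0.26), SWI/SNF (-0.16), p53 target (-0.20), Polycomb (-0.22) and endothelial genes (-1.27), besides the ATF4 list.

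The nascent ratio moved with the RNA level measured at day 7, a division chosen after the data were examined. The 2682 genes listed at 0 FPKM at day 7 had a median log2 ratio of -0.98 relative to all genes, and 411 of them were higher and 1207 lower in the knockdown library. The genes with day 7 RNA were divided into 3 classes of near-equal size, and the 1888 genes in the highest class had a median 0.84 above all genes, with 861 higher and 240 lower. The medians of the highest class and of the genes at 0 FPKM differed by 1.82 (95% bootstrap interval over genes 1.66 to 1.98). Across 8345 genes, nascent counts per kb of transcript in the knockdown library correlated with day 7 RNA at a Spearman rho of 0.317 (0.296 to 0.338), and those in the control library at -0.029. Over the 6339 genes at 1 FPKM or more at day 7, with no GRO-seq count minimum, these were 0.327 and 0.218, and over the 3606 of them with a summed count of at least 50 they were 0.352 and 0.176. Transcript length had a rho of -0.023 with the log2 ratio. These correlations are across genes, which are not independent replicates, and the assays sampled different days. Day 7 RNA came from knockdown cells only, so the control library was compared with RNA of the other condition.

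**Figure D3:**
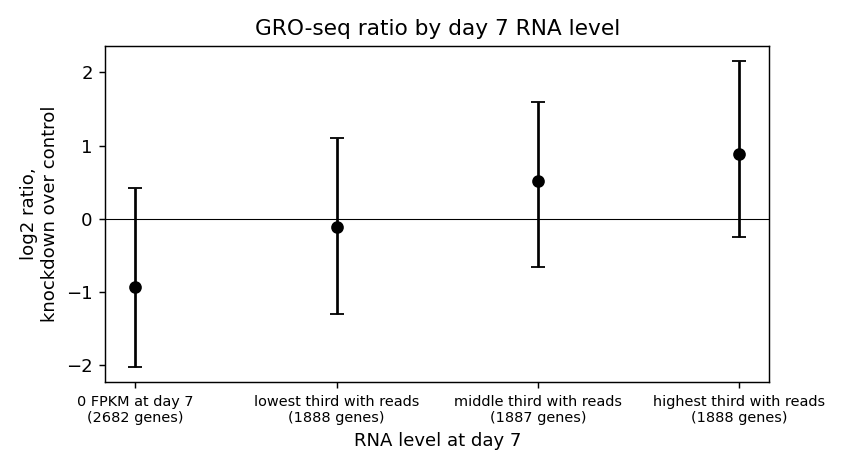
Median log2 ratio of nascent RNA (knockdown over control, vertical axis) for genes grouped by RNA level at day 7 (horizontal axis, number of genes in parentheses), with bars from the lower to the upper quartile. The median goes from -0.93 for genes at 0 FPKM to 0.89 for the highest class with reads.

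After 7 days of doxycycline, total RNA of ARID1A was represented by 0 reads in replicate 1 and 1 read in replicate 2, and that of ARID1B by 7 and 11 reads. Per kb of transcript, ARID1B was 32.0 times as abundant as ARID1A over both libraries (counting interval 5.05 to 1333) and 19.3 times in replicate 2 alone (2.81 to 832). Among the 28 SWI/SNF subunit genes the median was 0.925 FPKM and 12 reached 1 FPKM. SMARCE1 was the highest at 15.8 ± 5.90 FPKM (SD, n = 2), followed by ACTL6A at 11.1 ± 1.56 and SMARCD2 at 5.18 ± 2.63. These levels rested on 73, 8 and 5 reads over both libraries, so those of ACTL6A and SMARCD2 and their ranks are uncertain. Of the 27 subunits other than ARID1A, 9 had 1 read or fewer over both libraries, and the core subunit gene SMARCB1 and the ATPase gene SMARCA2 had 0. Of 8 common reference genes, 3 had 20 reads or fewer over both libraries (GAPDH with 12, HPRT1 with 11 and TBP with 0). The others had 22 (PPIA) to 483 reads (B2M), and the median of the 8 was 44.5. With no control library at day 7 analysed here and this depth, no loss of ARID1A RNA can be measured.

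**Figure D4:**
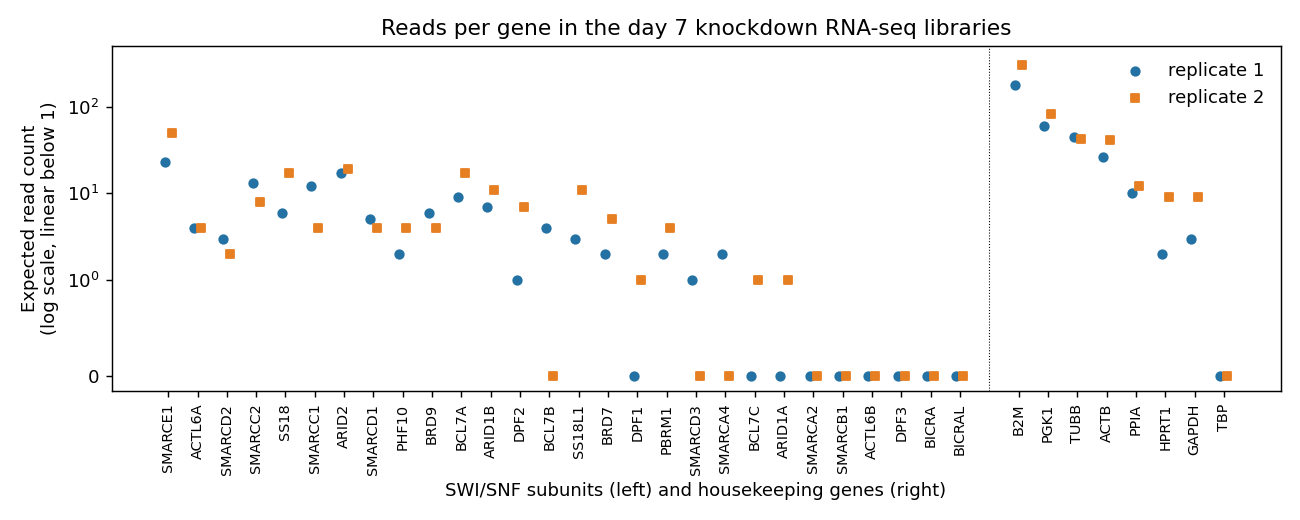
Estimated reads per gene (vertical axis, log scale, linear below 1) in the day 7 knockdown libraries, replicate 1 as circles and replicate 2 as squares, for 28 SWI/SNF subunits (left of the dotted line, ordered by mean FPKM) and 8 housekeeping genes (right). ARID1A had 0 reads and 1 read, and 9 of the 27 other subunits had 1 read or fewer over both libraries.

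The day 7 libraries were dominated by mitochondrial ribosomal RNA, with MT-RNR1 and MT-RNR2 taking 78.9% and 77.4% of reads and leaving 279719 and 425650 reads for all other genes. Next in level were the small structural RNAs RNA5-8SP6 (17261 FPKM) and 7SK (13518), the respiratory genes MT-ND4 (12849) and MT-ND4L (9392) and the nuclear non-coding RNA MALAT1 (9129). Among nuclear coding genes of the lists, the endoplasmic reticulum chaperone genes HSPA5 at 697 ± 4.72 FPKM (SD, n = 2) and HSP90B1 at 320.0 ± 12.6 stood highest. Of the clear cell carcinoma markers 11 of 22 reached 1 FPKM, as did 12 of 23 epithelial genes, with CLDN1 at 192 ± 50.8, TFPI2 at 123 ± 13.3 and SPP1 at 113 ± 13.7 FPKM. RPL5 at 160.5 ± 3.47, the linker histone gene H1-2 at 154 ± 2.22 and the chaperone gene HSP90AA1 at 125 ± 16.6 FPKM led their groups. Of 43 ribosomal protein genes 42 reached 1 FPKM, as did 26 of 31 pausing and elongation factor genes, led by ELL2 at 39.6 ± 6.55 FPKM. Of the other cell types, 0 of 18 immune, 1 of 12 fibroblast, 1 of 11 endothelial (ENG, with 3 reads in replicate 1 and 0 in replicate 2) and 2 of 14 neuronal markers reached 1 FPKM.

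In total 6339 genes reached a mean of 1 FPKM at day 7, with a median of 14 reads per gene over both libraries. The replicates correlated across these genes at a Pearson r of 0.429 and a Spearman rho of 0.509 on log2 FPKM, and at 0.930 and 0.894 over the 2613 genes with at least 20 reads. The replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.46 for genes of 5 to 20 reads and 105 for genes of 1000 or more. At a given relative difference this measure grows with the number of reads, so it does not rank the classes by reproducibility. The 6 largest differences were in the 5S ribosomal RNA pseudogenes RNA5SP113, RNA5SP338, RNA5SP68, RNA5SP302 and RNA5SP429 and the small nucleolar RNA gene SNORD99, each listed at 0 FPKM in replicate 2. These had 3 to 18 reads over both libraries. SNORD99 had 1 read in replicate 1 and 2 in replicate 2, so its FPKM difference runs against its reads.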

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

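Scaling over all genes in the tables, count minimums with the scaling kept, list medians relative to all genes at other minimums, matching on day 7 RNA level and the relations restricted to genes at 1 FPKM or more were chosen after the data were examined. The 2375 genes higher and 2322 lower became 911 and 909 at a summed count of at least 200, where fewer genes entered (3220), and 848 and 977 with the scaling kept. With no count filter (32780 genes), 4765 were higher and 2617 lower with the scaling recomputed, against 3227 and 4807 with it kept, so the excess of higher genes there came from the scaling. At a minimum of 20 with the scaling kept, 3034 were higher and 3595 lower. With TMM over all genes, 1499 were lower, 68.6% of the genes past the rule were higher, and ARID1A stood at -0.36, because that scaling adds the same shift to every gene. With total counts ARID1A stood at -1.03 and passed the 2-fold rule. DESeq2 factors, total counts and upper-quartile scaling gave 2236 to 2623 genes higher and 2081 to 2461 lower. The median log2 ratio of ATF4 and unfolded protein response genes was 0.85 and turned to -0.038 at a summed count of at least 200 (16 genes, scaling recomputed), and its percentile of 98.5 and that of histones (98.9) came to 82.6 and 96.0 when random lists were also matched on day 7 level; the cause was not tested. Genes at day 7 numbered 2283 at 5 FPKM, and the replicate r was 0.69 with a pseudocount of 1 and 0.56 with no minimum. The rho of nascent with day 7 RNA was -0.029 with the control library, 0.21 at a summed count of at least 200, 0.28 to 0.29 leaving out a day 7 replicate and, for the control library over genes at 1 FPKM or more with no count minimum, 0.22, while with a summed count of at least 50 as well it was 0.352 in the knockdown and 0.176 in the control library; the cause was not tested. The ratio of ARID1B to ARID1A was 19.3 without replicate 1 and had no value without replicate 2. Of 165 list medians under alternatives, 150 stayed within their interval and 14 moved, and further lists changed sign relative to all genes at count minimums of 20 or 200, as given in the results. Of 640 other values of named genes, 595 stayed within their interval and 45 moved without changing direction. No paired analysis was possible because each GRO-seq condition had 1 library.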

Other observations

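All tests in this part were chosen after the results they bear on had been seen, and the background test, first run without thinning and with LINC00486 kept, was revised and repeated after its result was known.

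The nascent log2 ratio spread far more widely between genes than counting allows. Counting error alone is argued against, since the interquartile range was 9.49 times that of redrawn counts. Libraries grown from few starting molecules, each read many times, may contribute: at 50 to 500 summed counts the SD of the log2 ratio was larger in the shortest of 5 length classes of genes than in the longest by 0.521 (0.392 to 0.654), 2.35 against 1.83, while the interquartile range followed length less regularly (3.03, 2.85, 2.98, 2.61 and 2.55 from shortest to longest). The choice of the SD was made with both measures in view. The shortest class (30 to 943 bases) may also differ from the longest in kind of gene, which was not examined. The difference in SD therefore does not single out few starting molecules. A knockdown effect, or one of doxycycline itself, stays open and untested, since each condition had 1 library.

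Genes with RNA at day 7 had higher nascent ratios than genes without. More background reads in the control library is a candidate explanation: among 21685 genes with no day 7 read, leaving out LINC00486, control counts thinned to the same number of reads over these genes followed transcript length with a rho higher by 0.104 (0.0931 to 0.115), 0.347 against 0.243, with 18658 against 14041 genes detected. These genes took 35.2% of control and 24.7% of knockdown counts other than LINC00486, which restates the pattern and supports no explanation. With control counts thinned further, to 14042 genes detected, the difference was 0.0727 (0.0615 to 0.0837). Few starting molecules in the knockdown library, each read many times, could also weaken the relation to length there. Thinning does not reproduce this, so the test cannot separate it from background in the control library. Mature RNA carried over into the knockdown library stays open. Among genes at 1 FPKM or more with a summed count of at least 50 the ratio increased with day 7 level at a rho of 0.142 (0.109 to 0.172). This likewise restates the pattern and decides nothing. Effects of ARID1A depletion, of doxycycline itself and of GC content were not tested.

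The single ARID1A read at day 7 could reflect the knockdown or the low recovery of many transcripts. Of the 27 other SWI/SNF subunit genes, 33.3% also had 1 read or fewer, and 3 of 8 housekeeping genes had 20 reads or fewer. BICRA, among these subunits, had 0 counts in both GRO-seq libraries too. Subunits silent in these cells would also have few reads, so the share is no measure of low recovery alone. The explanations for ARID1A therefore cannot be told apart without a control library of the same assay.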
